A study of Homo sapiens with 6 samples.

How the data were processed

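RNA-seq of total RNA was compared between 3 control libraries and 3 libraries of IL-1β-treated human fibroblast-like synoviocytes (10 ng/mL, 24 h). Per the labels' protocols, ribosomal RNA was depleted with Qiagen FastSelect. Per the submitters' processing notes, the authors used bcl2fastq, STAR 2.7.9a, Subread and featureCounts 2.0.3, and the build named there is GRCm38, a mouse assembly. The gene IDs are human Ensembl IDs, and 45038 of the 60671 features (77.05% of those that GENCODE release 29 holds) had the chromosome, start and end of GENCODE 29 on GRCh38. Coordinates are therefore given as the deposited tables give them, on GRCh38. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and reads shared by near-identical genes can be lost or divided.

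Each deposited table holds one library with 3 units per the file headers. The count column gives the authors' raw read counts per gene, and these counts were the input of every test. The deposited CPM column equals the count over the library's total count, to within 5.1e-11, in all 6 libraries. The deposited FPKM column equals that CPM per kilobase of the listed gene length, to within 1.4e-10. Neither normalised column was used further. Library totals were 33191275 to 45887443 counts. No row lacked a gene name, and 60401 features matched a symbol in a table of gene names. Intervals and floors cover counting error only, because counts were pooled over the libraries of a group. Reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for that error. Nuclear ribosomal RNA took 0.0012 to 0.002% of counts.

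Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, scaled by TMM, and tested with glmQLFit (robust) and glmQLFTest, with Benjamini-Hochberg adjustment over 19424 genes and a threshold of 0.05. Calls of at least 2-fold also needed an absolute log2 fold change of 1. SEs are the absolute log2 fold change over the square root of F. CPM values printed are counts over TMM-scaled library sizes. Gene lists were tested on log2 CPM (prior count 2) with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry from limma 3.58.1, adjusted over 23 lists with at least 3 tested genes out of 24 lists fixed. camera compares a list with the other genes, while fry asks whether a list's own genes move, on balance, one way. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

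The groups, tests, 24 lists, rule for named genes and alternatives were fixed before the data were examined. The rule named the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with at least 5 CPM in a group and no overlap between groups, the 2 largest changes past the threshold in each list, and 17 genes whatever their result. Only 6 genes fell in the unpaired fit. The rule was repeated on the paired fit, which was decided after the data were seen. Other genes named were chosen after their values were seen. Genes specific to one sex were kept in the fits and left out of every printed table. The values of 1 gene that the rule named are not reported here.

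The replicate number was shared by the groups, without a statement that it marks a donor. The correlation over genes of a library's deviations from its group mean was 0.52, 0.52 and 0.63 for libraries of the same number, against -0.44 to 0.03 for other numbers across groups, so every pair exceeded 0.1 and the numbers were taken to pair the samples. Deviations cancel within a group for each gene, so high values for the same number by themselves lower the values for other numbers. The pairing thus comes from the numbers in the labels and this check. The paired fit adds the number as a block. No 2 libraries agreed within sampling noise: chi-square per degree of freedom was 102 to 422 over pairs of libraries.

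The fits were tested on simulated counts for the 18322 genes that passed the filter there, drawn from the means, number effects and dispersions of the paired model and the real library sizes, with 200 well-expressed genes changed. For the IL-1β comparison, edgeR without the block recovered 4.5% of 2-fold, 44.8% of 4-fold and 77.3% of 8-fold changes, with 1 false call among 85. With the block it recovered 61.2%, 89.6% and 100%, with 14 false calls among 181 (7.7%). DESeq2 1.42.0 without the block recovered 28.4%, 83.6% and 98.5%, with 3 false calls among 143 (2.1%). With the block DESeq2 recovered 74.6%, 95.5% and 100%, with 38 false calls among 218 (17.4%). A simulated list of 20 genes raised 4-fold was called by camera with the preset correlation in both fits and by fry in both. With an estimated correlation camera called it without the block and missed it with the block.

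Alternatives were RLE, upper-quartile or no composition scaling, no filter, a filter of 10 counts in 3 libraries, DESeq2, limma-voom, the replicate block, protein-coding nuclear genes only, a threshold of 0.01, glmTreat, and leaving out each library. Both libraries of replicate 3 were also left out, and the paired fit was repeated with other tools, scalings and pairs left out, as choices added after the data were seen.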

Results

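Gene expression was measured by RNA-seq in 6 libraries of human fibroblast-like synoviocytes, the fibroblasts that line joints and secrete matrix, proteases and cytokines into them. The cells were primary and described as normal. A control group of 3 libraries was compared with 3 libraries of cells given interleukin-1β (IL-1β), an inflammatory cytokine, at 10 ng/mL for 24 h. Replicates carried the numbers 1 to 3 in both groups. The series asks how TGF-β1 affects chemokines induced by IL-1β, and cells given TGF-β1 were not analysed here, so the single comparison is IL-1β against control. Total counts were 45887443, 41373073 and 43205421 in control replicates 1 to 3 and 44211576, 42276514 and 33191275 in IL-1β replicates 1 to 3. At this depth 3 counts in a control library corresponded to 0.0692 CPM (counts scaled to a common library size) on average. The labels do not say whether replicates came from separate donors or cultures, so p-values measure the spread between these samples only. CPM values are means ± SD over n = 3 libraries, log2 fold changes carry their SE, and adjusted p-values are from edgeR's quasi-likelihood test unless another tool is named.

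Replicate 3 stood apart from the other libraries by more than treatment did. By correlation of log2 CPM, replicates 1 and 2 lay only slightly closer within a treatment than across it. These correlations were 0.9618 in controls and 0.9644 after IL-1β, and 0.9601 and 0.9611 for equal numbers across treatment. The first principal component, with 43.0% of the variance, set both libraries of replicate 3 apart from the other 4. The second, with 23.9%, separated IL-1β from control, and the third, with 17.0%, parted replicate 1 from replicate 2. Libraries with the same number deviated together from their group means, so a fit with the number as a block (the paired fit) is given beside the unpaired fit wherever it changed a call. Macrophage and leukocyte markers were far higher in both libraries of replicate 3. C1QB, a subunit of complement C1q made by macrophages, stood at 5.09, 0.44 and 83.2 CPM in control replicates 1 to 3 and at 2.72, 0.19 and 56.5 CPM in the IL-1β replicates. Of 12 tested markers of that list, 11 were highest in both libraries of replicate 3. Replicate 3 was also set against the mean of replicates 1 and 2, with 0.01 CPM added to both. The median ratio over all 12 markers was 24.2 among controls and 38.7 among IL-1β libraries. All 22 proliferation genes were lower in both libraries of replicate 3. The 10 most abundant genes of each library took 15.9 ± 1.01% of counts in controls and 13.5 ± 0.95% after IL-1β, and the mitochondrial share was 3.43 ± 0.84% and 2.79 ± 0.66%. Two-sided exact permutation tests gave p = 0.1 for the first share, the smallest that 3 against 3 libraries allow, and p = 0.4 for the second, which was lower after IL-1β in 3 of 3 pairs.

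**Figure D1:**
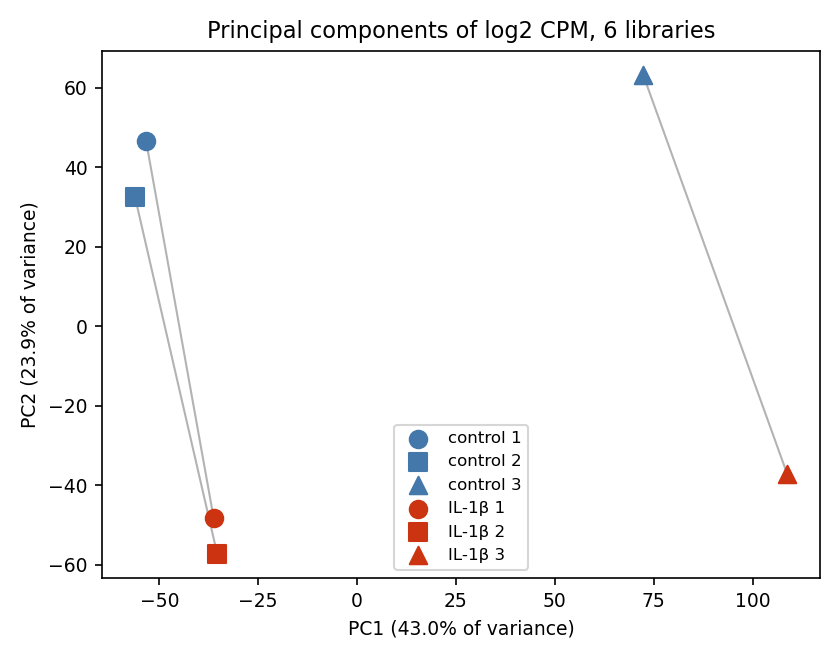
Principal components 1 and 2 of log2 CPM over the tested genes, with 43.0% and 23.9% of the variance on the axes. Each point is a library, colours mark treatment, shapes mark replicate number, and grey lines join libraries of the same number. Replicate 3 lies to the right in both groups and IL-1β libraries lie below the controls.

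IL-1β raised some chemokine, cytokine, NF-κB and metalloproteinase genes and lowered a smaller set of genes. In the unpaired fit 65 of 19424 tested genes passed, 59 higher and 6 lower, and 64 of them changed at least 2-fold, 58 higher and 6 lower. The paired fit called 1046 genes, 645 higher and 401 lower, of which 543 changed at least 2-fold, 370 higher and 173 lower. All 65 unpaired calls were among the paired calls with the same sign. No overlap between the groups' libraries was found for 15.9% of genes. Chance gives 10% for 3 against 3 libraries that are interchangeable, which the shared number effects speak against. All 3 pairs moved the same way for 44.2% of genes, against 25% by chance. The biological coefficient of variation was 45.9% without the block and 22.7% with it. The unpaired count rested on several libraries, at 0 without control replicate 1 or control replicate 2, 18 without control replicate 3, 11 without IL-1β replicate 1 and 4 without IL-1β replicate 2. At an unadjusted p under 0.05, edgeR counted 1352 and 1385 genes in the fits that called 0, against 1812 with all libraries. Chance alone would give 971 of the 19424 genes tested with all libraries. The paired count was 174 without pair 1, 228 without pair 2 and 3256 without pair 3, and the unpaired count without both libraries of replicate 3 was 174.

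Some CXC chemokine genes, whose products mostly attract neutrophils, rose strongly. CXCL6 rose from 8.31 ± 1.26 to 3190 ± 2121 CPM (log2 fold change 8.58 ± 0.88, adjusted p = 0.0285). CXCL1 rose from 24.0 ± 1.97 to 3453 ± 1885 CPM (7.17 ± 0.61, adjusted p = 0.0178) and CXCL3 from 3.54 ± 1.18 to 409 ± 99.8 CPM (6.85 ± 0.38, adjusted p = 0.00672). CXCL8, which encodes interleukin-8, stood at 2.10 ± 2.78 and 1832 ± 877 CPM. Its log2 fold change of 9.77 ± 1.43 did not pass unpaired (adjusted p = 0.0747) and it rose in the paired fit (10.36 ± 0.75, adjusted p = 0.0084). CXCL5 likewise rose only in the paired fit (8.50 ± 0.22, adjusted p = 5.54e-05, against 0.0655 unpaired). Of 14 listed CXC and CX3C chemokines 10 were expressed enough to test. Unpaired, 3 rose, 0 fell and 7 did not pass, and 8 were higher adjusted over the list alone. With the block 8 rose and 2 did not pass, with 8 higher adjusted over the list alone. CXCL10, an interferon-inducible chemokine, was too low to test, with 0 counts in the controls and 0.098 ± 0.132 CPM after IL-1β. The list was higher than other genes (camera adjusted p = 8.59e-13, and adjusted p = 0.0358 with an estimated correlation), but it did not pass with an estimated correlation and the block (adjusted p = 0.253). These genes lie together on chromosome 4 of GRCh38, CXCL8 at 73740541 to 73743716, CXCL6 at 73836640 to 73849064, CXCL1 at 73869393 to 73871308, CXCL5 at 73995642 to 73998677 and CXCL3 at 74036589 to 74038807. CXCL1 and CXCL3, and CXCL5 and CXCL6, are close paralogs whose reads may have been divided or dropped in counting.

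Of the CC chemokines 1 rose in both fits. CCL2, which attracts monocytes and lies on chromosome 17 at 34255218 to 34257203, went from 45.5 ± 21.7 to 659 ± 108 CPM (3.86 ± 0.38, adjusted p = 0.0274). CCL5, a chemokine for T cells and monocytes, stood at 0.126 ± 0.147 and 20.4 ± 4.54 CPM (7.28 ± 0.94, adjusted p = 0.0563 unpaired) and rose in the paired fit (adjusted p = 0.00679). CCL20 stood at 0.169 ± 0.196 and 119 ± 179 CPM (9.44 ± 1.97, adjusted p = 0.189) and also rose in the paired fit (9.32 ± 0.46, adjusted p = 0.00185). IL-1β replicate 3, where macrophage markers were high, held 326 CPM of CCL20, against 14.4 and 17.8 CPM in IL-1β replicates 1 and 2. Of 16 CC chemokines 10 were tested. Unpaired, 1 rose, 0 fell and 9 did not pass, with 6 higher adjusted over the list alone. Paired, 5 rose and 5 did not pass, with 8 higher adjusted over the list alone. The list passed (camera adjusted p = 1.07e-09), but not with an estimated correlation (adjusted p = 0.0532).

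**Figure D2:**
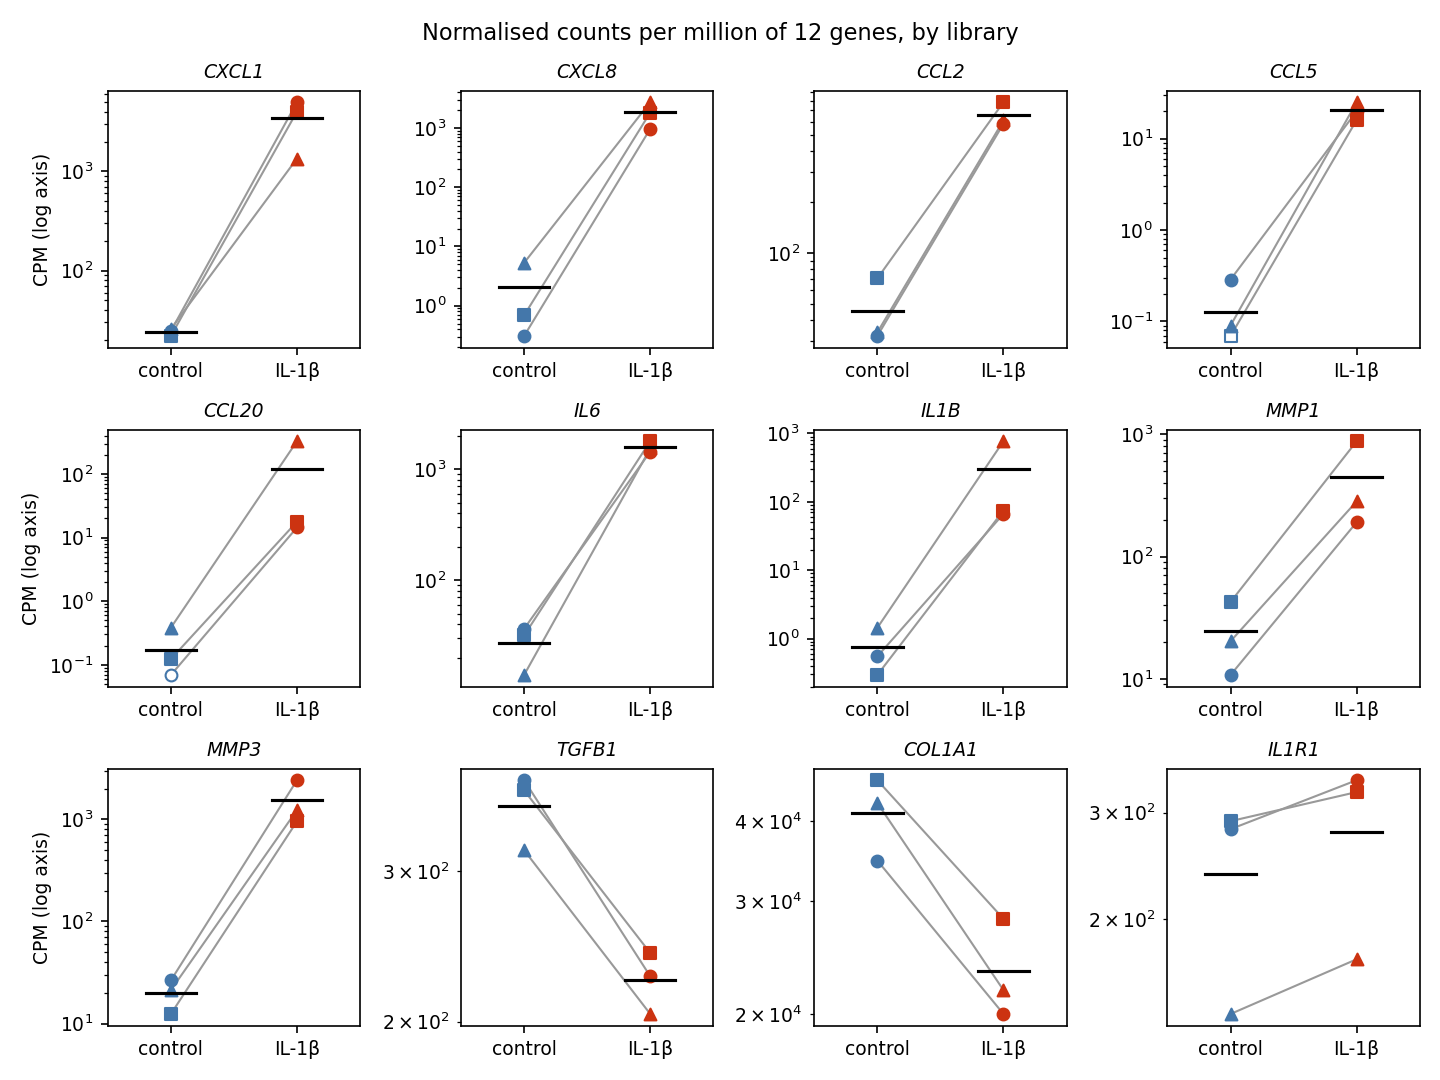
CPM of 12 genes on log axes, with a panel per gene and its own scale. Blue points are controls, red points IL-1β, shapes mark the replicate number, grey lines join equal numbers, black bars are group means, and open points lie under the floor of 0.0692 CPM and are drawn on it. CXCL1 goes from 24.0 to 3453 CPM on average, COL1A1 from 41250 to 23332 CPM.

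Some interleukin and colony-stimulating factor genes rose. IL6, a pro-inflammatory cytokine on chromosome 7 at 22725884 to 22732002, went from 27.5 ± 11.9 to 1583 ± 180 CPM (5.85 ± 0.45, adjusted p = 0.0151). CSF3, the granulocyte colony-stimulating factor gene, went from 0.103 ± 0.082 to 153 ± 125 CPM (10.53 ± 0.99, adjusted p = 0.0266). IL33 rose from 0.160 ± 0.096 to 11.1 ± 4.53 CPM (6.08 ± 0.57, adjusted p = 0.0213) and IL11 from 3.51 to 150 CPM (5.42, adjusted p = 0.0398). CSF2 had 0 counts in every control library and 8.39 ± 8.95 CPM after IL-1β, at least 121-fold higher against a floor of 3 counts per library. That bound leans on replicate 3, as CSF2 stood at 2.45, 4.03 and 18.7 CPM in IL-1β replicates 1 to 3. CSF2 rose in the paired fit only (adjusted p = 0.00327, against 0.177 unpaired). IL1B itself stood at 0.763 ± 0.602 and 304 ± 405 CPM (8.63 ± 1.49, adjusted p = 0.127) and rose in the paired fit (8.18 ± 0.50, adjusted p = 0.00549). Its level was 66.8, 74.8 and 772 CPM in IL-1β replicates 1 to 3. Of 24 listed genes 23 were tested. Without the block 4 rose, 0 fell and 19 did not pass, with 15 higher adjusted over the list alone, and with it 14 rose and 9 did not pass, with 18 higher adjusted over the list alone. The list passed with the preset correlation (camera adjusted p = 5.1e-19) and with an estimated correlation (adjusted p = 0.0122), but not with an estimated correlation and the block (adjusted p = 0.253).

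Some genes of the list of NF-κB factors and feedback inhibitors rose. ZC3H12A, which encodes the ribonuclease regnase-1 that degrades cytokine mRNAs, went from 9.11 ± 1.31 to 139 ± 25.6 CPM (3.93 ± 0.20, adjusted p = 0.00672). TNIP3, which encodes a partner of the inhibitor A20, rose from 0.861 ± 0.379 to 18.6 ± 8.47 CPM (4.42 ± 0.49, adjusted p = 0.0353). NFKBIZ (3.08, adjusted p = 0.0137), NFKBIA (2.57, adjusted p = 0.021) and the factor gene NFKB2 (adjusted p = 0.0312) rose too. Of 18 listed genes 5 rose unpaired, 0 fell and 13 did not pass, with 15 higher adjusted over the list alone. When paired 11 rose and 7 did not pass, with 16 higher adjusted over the list alone. The list passed (camera adjusted p = 2.54e-21) but not with an estimated correlation (adjusted p = 0.0532). Among 13 tested genes of the IL-1 receptor and its adaptors, 1 rose in both fits, IRAK3, an inhibitory kinase-like protein (22.7 ± 2.38 to 85.8 ± 9.27 CPM, 1.92 ± 0.14, adjusted p = 0.0137), and 12 did not pass. Adjusted over the list alone, 1 was higher unpaired and 2 in the paired fit. The receptor gene IL1R1 stood at 237 ± 84.7 and 278 ± 92.7 CPM (0.23 ± 0.38, adjusted p = 0.94). That list did not pass with camera (adjusted p = 0.34, and adjusted p = 0.733 with an estimated correlation) and passed with fry and the block (adjusted p = 0.0222).

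Metalloproteinases, enzymes that cleave matrix, passed as a list in the higher direction (camera adjusted p = 0.000185) but not with an estimated correlation (adjusted p = 0.0532). MMP3, or stromelysin-1, rose from 20.04 ± 7.10 to 1541 ± 780 CPM (6.26 ± 0.55, adjusted p = 0.0185). MMP1, an interstitial collagenase, stood at 24.5 ± 16.3 and 450 ± 372 CPM (adjusted p = 0.166) and rose in the paired fit (4.11 ± 0.14, adjusted p = 0.000106). MMP12, macrophage elastase, had 2 counts in the controls together and 5673 in the IL-1β libraries, a ratio of 3088 with an exact 95% counting interval of 854 to 25500, and it passed only when paired (adjusted p = 4.45e-05, against 0.129). Its level was highest in IL-1β replicate 3, at 140 CPM against 22.0 and 4.15 CPM. MMP13, another collagenase, stood at 7.18 ± 10.8 and 22.1 ± 27.8 CPM (1.63 ± 1.61, adjusted p = 0.861) and rose in the paired fit (2.25 ± 0.37, adjusted p = 0.0376). MMP1, MMP3, MMP12 and MMP13 lie on chromosome 11 between 102789919 and 102955732. Of 19 listed genes 1 rose unpaired, 0 fell and 18 did not pass, with 4 higher adjusted over the list alone. With the block 7 rose, 1 fell (ADAMTS2) and 11 did not pass, with 12 higher and 3 lower adjusted over the list alone. Of 10 protease inhibitor genes, none passed unpaired, with 1 higher and 1 lower adjusted over the list alone. In the paired fit 2 rose, SERPINB2 (adjusted p = 0.0107) and SERPINE2 (1.58 ± 0.10, adjusted p = 0.00121), with 3 higher and 3 lower adjusted over the list alone. SERPINB2 had 8 counts in the controls and 287 after IL-1β, a ratio of 39.05 with an exact 95% counting interval of 19.56 to 91.33. Replicates 1 to 3 held 6, 0 and 2 counts in the controls and 108, 16 and 163 after IL-1β, a spread that the interval does not cover. The protease inhibitor list did not pass (camera adjusted p = 0.992, and adjusted p = 0.993 with an estimated correlation).

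Collagen and matrix genes passed as a list in the lower direction (camera adjusted p = 0.00868) but not with an estimated correlation (adjusted p = 0.344), with fry (adjusted p = 0.176) or without control replicate 2 (adjusted p = 0.0724). With the block the list passed with camera (adjusted p = 0.00288) and with fry (adjusted p = 0.0436), but not with camera at an estimated correlation (adjusted p = 0.327). COL1A1, the α1 chain of type I collagen on chromosome 17 at 50184101 to 50201632, stood at 41250 ± 5936 and 23332 ± 4281 CPM (-0.82 ± 0.36, adjusted p = 0.569) and fell in the paired fit (-0.83 ± 0.11, adjusted p = 0.012). COL6A3 (-0.96 ± 0.10, adjusted p = 0.00583) and COL15A1 (-1.18 ± 0.17, adjusted p = 0.0169) also fell when paired. COL3A1 (0.58, adjusted p = 0.0277) and DCN (0.56, adjusted p = 0.0216) rose. None of the 33 listed genes passed unpaired, over all genes or adjusted over the list alone. With the block 7 fell, 2 rose and 24 did not pass, with 14 lower and 5 higher adjusted over the list alone. TGFB1, the gene of transforming growth factor β1, stood at 357 ± 35.3 and 224 ± 18.3 CPM (-0.68 ± 0.15, adjusted p = 0.209) and fell in the paired fit (-0.68 ± 0.09, adjusted p = 0.0123). It overlaps HNRNPUL1 on the opposite strand, which had a similar mean count (10582.5 against 12257.7), and CCDC97. Its receptor gene TGFBR2 stood at 182 ± 83.8 and 169 ± 50.8 CPM (-0.11 ± 0.43, adjusted p = 0.988, and 0.966 when paired). Among 23 TGF-β ligands, receptors and SMADs none passed unpaired, with 1 higher and 1 lower adjusted over the list alone. In the paired fit 2 rose, TGFBR1 (0.57, adjusted p = 0.034) and the co-repressor TGIF1 (1.01 ± 0.11, adjusted p = 0.00731), and 3 fell, TGFB1, ENG and LTBP2 (-0.90 ± 0.12, adjusted p = 0.0124), with 4 higher and 4 lower adjusted over the list alone. The list did not pass (camera adjusted p = 0.555, and adjusted p = 0.733 with an estimated correlation).

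Contractile and TGF-β-responsive genes did not pass as a list with all libraries and no block (camera adjusted p = 0.164) and passed with the block (adjusted p = 0.00288, and adjusted p = 0.327 with an estimated correlation and the block). Without the block the list also passed when control replicate 1 (adjusted p = 0.0427), control replicate 2 (0.0357), IL-1β replicate 3 (0.0101) or both libraries of replicate 3 (0.0286) were left out. ACTA2, smooth muscle actin, stood at 720 ± 622 and 418 ± 216 CPM (-0.79 ± 0.67, adjusted p = 0.826, and 0.174 when paired). None of 14 members passed unpaired, over all genes or adjusted over the list alone. TPM2 (-0.50 ± 0.10, adjusted p = 0.0397) and MYL9 (-0.48 ± 0.10, adjusted p = 0.0482) fell in the paired fit and 12 did not pass, with 8 lower adjusted over the list alone. Both genes were highest in replicate 3 in each group, MYL9 at 1768 CPM in control replicate 3 against 866 and 656 CPM.

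Prostaglandin genes, adhesion molecules and antioxidant genes each held strongly induced members. PTGES, the inducible prostaglandin E synthase, rose from 9.97 ± 2.24 to 241 ± 107 CPM (4.60 ± 0.45, adjusted p = 0.0277) and PLA2G4A, the cytosolic phospholipase A2, from 10.3 ± 1.48 to 46.6 ± 14.6 CPM (2.18 ± 0.27, adjusted p = 0.0439). PTGS2, or cyclooxygenase-2, stood at 39.5 and 994 CPM and passed neither fit (adjusted p = 0.103 unpaired and 0.0554 paired). Of 15 tested prostaglandin genes 2 rose unpaired and 13 did not pass, with 3 higher adjusted over the list alone. When paired 3 rose and 12 did not pass, with 5 higher adjusted over the list alone. This list did not pass with all libraries and no block (camera adjusted p = 0.0552) and passed with the block (adjusted p = 0.0247, and adjusted p = 0.327 with an estimated correlation and the block). Without the block it also passed when control replicate 1 (adjusted p = 0.0243), IL-1β replicate 2 (0.0492), IL-1β replicate 3 (0.0155) or both libraries of replicate 3 (0.0195) were left out. CD82, a tetraspanin, rose from 13.0 ± 6.11 to 117 ± 10.9 CPM (3.17 ± 0.36, adjusted p = 0.0377) and was 1 of 17 tested adhesion genes past the threshold, with 3 higher adjusted over the list alone. SELE had 0 control counts and 0.894 ± 0.917 CPM after IL-1β, at least 12.9-fold higher against 3 counts per library. That bound leans on replicate 3, as SELE stood at 0.402, 0.328 and 1.95 CPM in IL-1β replicates 1 to 3. SELE passed in the paired fit only (adjusted p = 0.0468, against 0.248). In that fit 2 adhesion genes rose, 2 fell and 13 did not pass, with 5 higher and 2 lower adjusted over the list alone. The adhesion list passed (camera adjusted p = 0.00117) but not with an estimated correlation (adjusted p = 0.225). SOD2, mitochondrial superoxide dismutase, rose from 242 ± 110 to 5929 ± 1746 CPM (4.61 ± 0.47, adjusted p = 0.0277). It was 1 of 17 antioxidant and metallothionein genes past the threshold unpaired, with 7 higher and 2 lower adjusted over the list alone. In the paired fit 4 rose and 2 fell, NQO1 (-0.88, adjusted p = 0.0178) and GCLC (-0.84, adjusted p = 0.0293), with 7 higher and 3 lower adjusted over the list alone. MT1F, a metallothionein with near-identical relatives, was among those that rose when paired (3.38 ± 0.36, adjusted p = 0.00661). The list did not pass (camera adjusted p = 0.0612, and adjusted p = 0.471 with an estimated correlation).

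**Figure D3:**
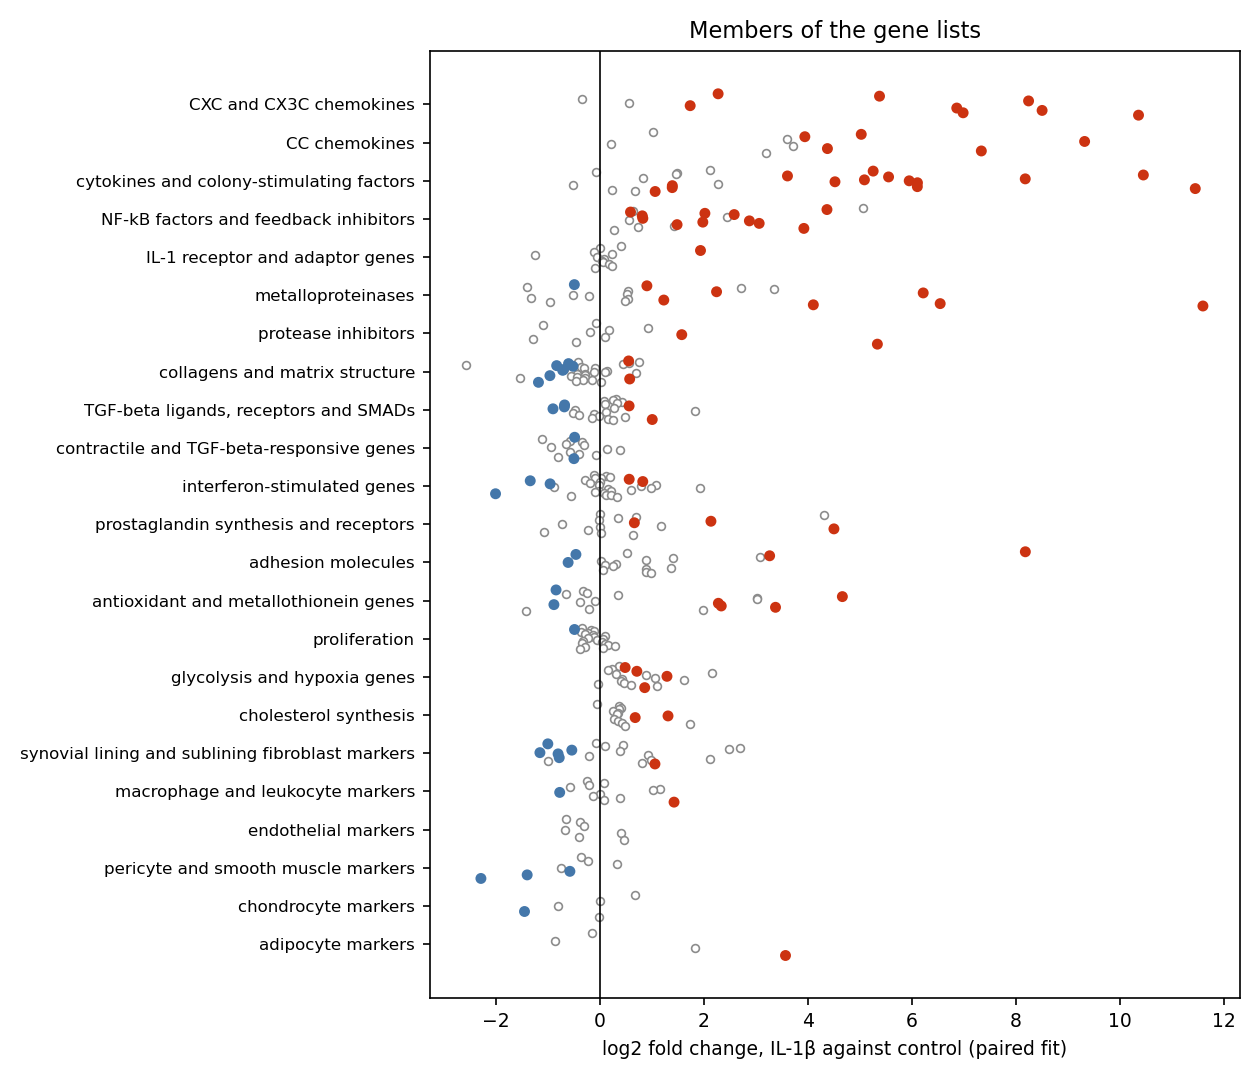
Paired log2 fold changes, IL-1β against control, of the tested members of 23 gene lists. Each point is a gene, red points rose and blue points fell at an adjusted p under 0.05, and open points did not pass. Values of CSF2, MMP12 and SELE rest on controls with 0 to 2 counts in all. Of the chemokine and cytokine lists 8 of 10, 5 of 10 and 14 of 23 members rose.

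None of 18 glycolysis and hypoxia genes passed unpaired, over all genes or adjusted over the list alone. When paired 4 rose, among them PFKFB4 (1.29 ± 0.18, adjusted p = 0.015) and BNIP3 (0.86 ± 0.11, adjusted p = 0.00966), and 14 did not pass, with 10 higher adjusted over the list alone. That list passed (camera adjusted p = 0.0011) but not with an estimated correlation (adjusted p = 0.57) or without IL-1β replicate 3 (adjusted p = 0.491). It passed without both libraries of replicate 3 (adjusted p = 0.00346). With the block it passed too (adjusted p = 4.11e-06, and adjusted p = 0.479 with an estimated correlation and the block). BNIP3 was highest in replicate 3 in both groups, at 139 CPM against 52.5 and 52.5 CPM in controls and 297 CPM against 87.8 and 88.7 CPM after IL-1β. None of 14 cholesterol synthesis genes passed unpaired, with 1 higher adjusted over the list alone. When paired 2 rose, among them LSS, which encodes lanosterol synthase (0.68 ± 0.11, adjusted p = 0.0216), and 12 did not pass, with 9 higher adjusted over the list alone. The list passed (camera adjusted p = 8.47e-06) but not with an estimated correlation (adjusted p = 0.273). Of 22 proliferation genes none passed unpaired, over all genes or adjusted over the list alone, and MCM6 fell when paired (-0.48 ± 0.09, adjusted p = 0.0329), as it did adjusted over the list alone. That list did not pass (camera adjusted p = 0.392, and adjusted p = 0.927 with an estimated correlation). Of 29 tested interferon-stimulated genes none passed unpaired, with 2 lower adjusted over the list alone. When paired 3 fell, IFIT1 (-2.00 ± 0.29, adjusted p = 0.015), IFIT2 (-1.33 ± 0.25, adjusted p = 0.0359) and XAF1, and 2 rose, GBP1 and IRF1, with 3 lower and 4 higher adjusted over the list alone. IFIT1 (mean count 89.8) and IFIT2 (153) overlap LIPA on the opposite strand, which had a far higher mean count of 2226.7. The list did not pass (camera adjusted p = 0.992, and adjusted p = 0.993 with an estimated correlation).

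Markers of cell types moved in part. Of 18 lining and sublining fibroblast markers none passed unpaired, with 1 higher adjusted over the list alone. In the paired fit 5 fell and DPP4 rose (1.06 ± 0.13, adjusted p = 0.0104), with 5 lower and 6 higher adjusted over the list alone. Among those that fell were PDGFRB (-1.15 ± 0.10, adjusted p = 0.00281), NOTCH3 (adjusted p = 0.00679) and PRG4, the gene of the joint lubricant lubricin (112 ± 95.9 and 56.6 ± 37.3 CPM, -0.80 ± 0.15, adjusted p = 0.0389, against 0.81 unpaired). PRG4 overlaps TPR on the opposite strand, which had a higher mean count (6065.2 against 3528.2). The list did not pass (camera adjusted p = 0.468, and adjusted p = 0.6 with an estimated correlation). Of 7 pericyte and smooth muscle markers none passed unpaired, with 2 lower adjusted over the list alone. In the paired fit DES (-2.28 ± 0.22, adjusted p = 0.0043), CSPG4 (-1.39 ± 0.10, adjusted p = 0.00154) and RGS5 fell and 4 did not pass, and 4 were lower adjusted over the list alone. That list passed (camera adjusted p = 0.0395) but not with an estimated correlation (adjusted p = 0.471), without both libraries of replicate 3 (adjusted p = 0.338), or without control replicate 3 (adjusted p = 0.653), IL-1β replicate 1 (adjusted p = 0.118) or IL-1β replicate 2 (adjusted p = 0.148). MYH11 stood at 529 CPM in control replicate 3 against 72.4 and 146 CPM in control replicates 1 and 2. Of 12 macrophage and leukocyte markers none passed unpaired, and when paired MRC1 rose (1.43 ± 0.27, adjusted p = 0.0453) and C1QB fell (-0.77 ± 0.15, adjusted p = 0.0393), the same 1 higher and 1 lower count as adjusted over the list alone. The list did not pass (camera adjusted p = 0.992, and adjusted p = 0.993 with an estimated correlation). Of 7 endothelial, 5 chondrocyte and 4 adipocyte markers none passed unpaired, over all genes or adjusted over each list alone. When paired the proteoglycan gene ACAN fell (-1.46 ± 0.19, adjusted p = 0.0131) and the lipase gene LPL rose (3.56 ± 0.25, adjusted p = 0.00154), each also past the threshold adjusted over its list alone, where 1 endothelial marker was lower. Camera adjusted p was 0.752 for endothelial, 0.296 for chondrocyte and 0.661 for adipocyte markers (with an estimated correlation adjusted p = 0.916, 0.471 and 0.733). None of 9 lymphocyte markers was expressed enough to test.

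**Figure D4:**
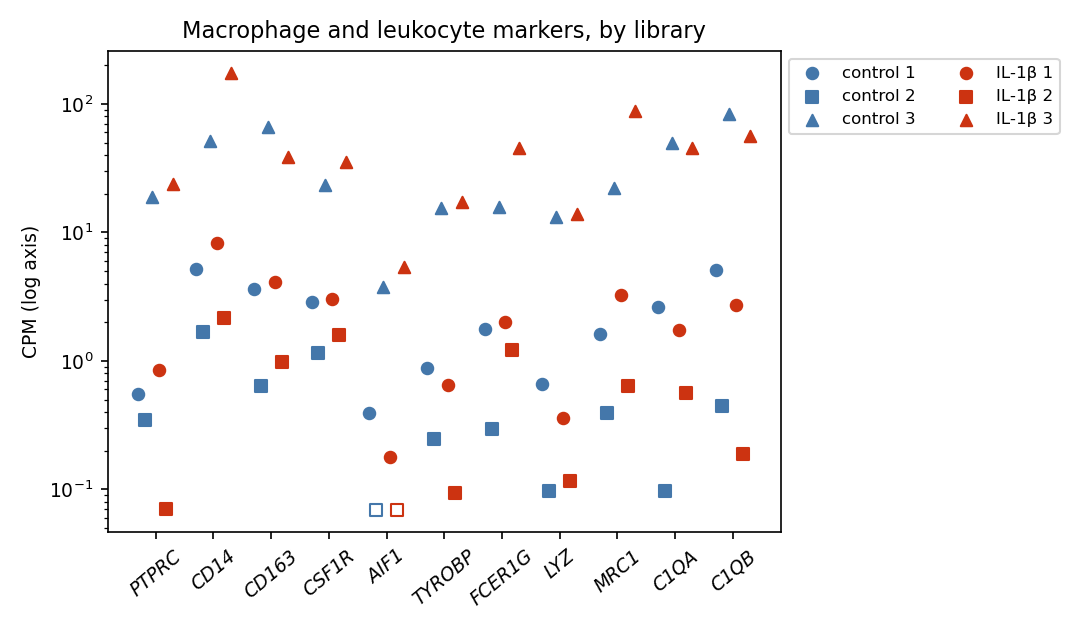
CPM of 11 macrophage and leukocyte markers with a mean of at least 1 CPM, on a log axis. Blue points are controls, red points IL-1β, shapes mark the replicate number, and open points lie under 0.0692 CPM and are drawn there. Triangles, the libraries of replicate 3, lie above the other shapes for every gene drawn, with C1QB at 83.2 and 56.5 CPM.

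Outside the lists, C15orf48 had 0 counts in the controls and 5.23 ± 2.35 CPM after IL-1β, at least 75.6-fold higher against 3 counts per library (adjusted p = 0.0436). It overlaps SLC30A4-AS1 on the same strand, which had a mean count of 67.3 against 99.2, and an antisense transcript. All 6 genes that fell in the unpaired fit were protein-coding. LMO7, a LIM domain protein, fell from 465 ± 105 to 133 ± 11 CPM (-1.81 ± 0.21, adjusted p = 0.0377) and ATP10A, a phospholipid flippase, from 227 ± 26.0 to 71.8 ± 4.87 CPM (-1.66 ± 0.14, adjusted p = 0.0178). SYNE3, a nuclear envelope protein, fell from 138 ± 17.9 to 47.2 ± 7.06 CPM (-1.55 ± 0.17, adjusted p = 0.0324). EFNB1, the ephrin-B1 gene on chromosome X at 68829021 to 68842160, fell from 48.8 ± 4.59 to 18.3 ± 0.10 CPM (-1.41 ± 0.12, adjusted p = 0.0178). TPD52L1 (-1.46 ± 0.16, adjusted p = 0.0357) and CCNYL1 (-1.08 ± 0.12, adjusted p = 0.0354) fell too, and TPD52L1 overlaps HDDC2 on the opposite strand. The largest falls of the paired fit under the same rule were in KRT16 (-5.63 ± 0.67, adjusted p = 0.0103), KRT14 (-3.81 ± 0.67, adjusted p = 0.0451), ANK3 (-3.30 ± 0.30, adjusted p = 0.0105), PRR33, TENT5B, KRT18 (-2.60 ± 0.24, adjusted p = 0.00457), LSP1 (-2.59 ± 0.12, adjusted p = 0.00034) and COL21A1. PRR33 lies within LSP1, KRT18 overlaps KRT8, and KRT14 and KRT16 are close paralogs. Of 22 genes of the naming rule that passed unpaired, 0 passed without control replicate 1 or control replicate 2, 6 without control replicate 3, 5 without IL-1β replicate 1, 2 without IL-1β replicate 2 and 17 without IL-1β replicate 3, and each kept its sign in all 6 of these fits.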

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

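The alternatives to the paired fit and the fits without both libraries of replicate 3 were chosen after the data were seen. The 65 calls were within 1.5 times under RLE, upper-quartile and library-size scaling, the 10-count filter, limma-voom and protein-coding nuclear genes only (60 to 69). They became 263 with no filter, 648 with DESeq2, 1046 with the replicate block, 174 without both libraries of replicate 3 and 4 at a threshold of 0.01, and 0 to 67 when 1 library was left out. The 64 calls of at least 2-fold became 203, 467, 543 and 166 under the first 4 of these settings, 15 with glmTreat, and 0 to 66 when 1 library was left out. Higher calls outnumbered lower ones in every setting with calls. With the replicate block, the 1046 calls became 1947 with DESeq2, of which 1040 were shared, 292 at a threshold of 0.01, and 174 to 3256 when 1 pair was left out, where 4 libraries leave 1 residual degree of freedom. The 10 lists past the threshold became 10 to 13 when 1 library was left out, 2 with an estimated correlation, 5 with fry, 8 with fry and the block, and 0 with an estimated correlation and the block, a setting that also missed the simulated list. For camera with the preset correlation the block added the contractile and prostaglandin lists and changed no other call. For fry it added the cholesterol, collagen and IL-1 receptor lists. The causes of these shifts were not tested. Apart from number effects the simulated genes were drawn independently, so the missed list cannot tell low power from correlation within the real lists.

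Of 352 values of the 22 named genes past the threshold, over 16 alternatives, 235 stayed past it, 117 did not and 0 changed sign. Among 49 genes not past it, 89 of 784 values passed and 9 changed sign, none of them past the threshold: IL1R1 (-0.031), ACTA2 (0.22), MYL9 (0.058) and C1QB (2.83) without control replicate 3, MMP13 without IL-1β replicate 2 (-0.22), MRC1 without IL-1β replicate 3 (-2.04), and TGFBR2 without control replicate 1 (0.097), control replicate 2 (0.103) or IL-1β replicate 3 (0.12). At the other end of the range with 1 library left out stood 0.48 for IL1R1, -1.29 for ACTA2, -0.98 for MYL9 and -4.34 for C1QB without IL-1β replicate 3, 4.50 for MMP13 without control replicate 2, and 4.93 for MRC1 and -0.44 for TGFBR2 without control replicate 3. Genes with 0 counts in the controls give bounds only, against a floor of 0.0692 CPM.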

Other observations

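The tests below on macrophage RNA, matrix genes and the splits of the unpaired fit were chosen after the results were seen. Those on pairings, on splits of the paired fit and on gene families were written first.

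Some single genes outside the lists changed in the paired edgeR fit as well, and they stand for no tested group. STC1, which encodes the hormone stanniocalcin-1, rose from 22.9 to 788 CPM (log2 fold change 5.14, adjusted p = 4.45e-05) and TFPI2, a serine protease inhibitor, from 33.8 to 816 CPM (4.65, adjusted p = 4.45e-05). The bradykinin receptor genes BDKRB1 (4.17, adjusted p = 0.00243) and BDKRB2 (2.72, adjusted p = 0.00269) both rose, as did the metal transporter genes SLC39A14 (2.38, adjusted p = 0.00057) and SLC11A2 (1.86, adjusted p = 0.000791). NAMPT, the rate-limiting enzyme of NAD salvage, rose from 39.4 to 488 CPM (3.61, adjusted p = 0.000528), and its pseudogene NAMPTP1 rose with it. Of these SLC39A14, SLC11A2, NAMPT and NAMPTP1 also passed unpaired. Complement C3 rose from 14.97 to 125 CPM (3.01, adjusted p = 0.000123). All 13 mitochondrially encoded protein genes were lower in 3 of 3 pairs (median log2 change -0.30) and 0 passed in edgeR. These genes were picked after their values were seen.

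Gene families defined by the letters of their symbols were tested for over-representation among paired calls with a one-sided Fisher's exact test, with 14237 tested protein-coding genes as background. Of 178 families with at least 10 members, in 2 directions, 6 passed. The test treats genes as independent, and members of a family can move together or share reads, so its p-values can be too small. The IL, CCL, MMP and COL families hold genes of the lists above and are no separate support for them. IL (14 of 51, adjusted p = 5.67e-06), CCL (5 of 11, adjusted p = 0.00449) and MMP (6 of 19, adjusted p = 0.00684) were over-represented among higher genes, and COL (8 of 38, adjusted p = 0.000689) among lower genes. Outside the lists, 5 of 10 oxysterol-binding protein genes (OSBPL, adjusted p = 0.00053) fell, where 0.27 were expected: OSBPL10 (-1.79), OSBPL6 (-1.04), OSBPL3 (-1.01), OSBPL1A (-0.56) and OSBPL9 (-0.42). Of 14 keratin genes 4 fell (KRT, adjusted p = 0.024), KRT16, KRT14, KRT18 and KRT7, where 0.37 were expected. KRT7 went from 242 to 97.7 CPM, while KRT16 in the controls came mostly from replicate 1 (14.5, 2.09 and 0.95 CPM). No explanation of these falls was tested.

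More genes passed with the replicate number as a block (1046) than without it (65). A candidate explanation is that libraries of the same number share a source such as a donor or culture. Of the 5 other ways of pairing libraries across groups, the highest called 99 genes and kept control 3 with IL-1β 3, and the others called 0 to 2. In edgeR the pairings that called 0 had 993 to 1375 genes at an unadjusted p under 0.05, against 3895 for the pairing by number. The comparison of pairings draws on the same likeness of libraries as the correlation check and is not separate support. What the numbers stand for stays open, because the labels do not say.

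The splits of the libraries are too few for a share under 0.05. The real split called 65 genes and the highest other split 0, and for at least 2-fold 64 and 0, so 1 of 10 splits reached the real count. In edgeR the real split had 1812 genes at an unadjusted p under 0.05, and the other splits had 93 to 1809. By that measure the real split barely exceeded the highest other. Chance alone would give 971 of 19424 genes. For the lists the real split called 10 and the highest other 9, with control replicates 1 and 2 and IL-1β replicate 2 on a side, a split that parts 1 pair and sets both libraries of replicate 3 together. Camera with a preset correlation thus also called lists in a split other than treatment. That side still held more controls than IL-1β libraries, so number and treatment cannot be told apart there. In the paired fit 1 of the 4 splits that part all 3 pairs reached 1046 genes, and the highest other called 0. At an unadjusted p under 0.05 in edgeR, the real split had 3895 genes and the others 118 to 612.

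Of the chemokine and cytokine genes 27 of 43 rose in the paired fit, while macrophage markers were high in replicate 3. For the tested genes, RNA of macrophages in those cultures as the only source of the rise is argued against by the other pairs. A gene silent in the controls passed the filter only with counts in all IL-1β libraries. Genes seen in replicate 3 alone were thus not tested, which tilts the medians of pairs 1 and 2 upwards. C1QB was also present in pair 1 (5.09 and 2.72 CPM) and lower in pair 2 (0.44 and 0.19 CPM). All 43 tested members of the 3 chemokine and cytokine lists, whether they passed or not, had a median log2 ratio of 3.63 in pair 1 (quartiles 1.41 and 5.63), 3.40 in pair 2 (1.27 and 6.13) and 3.26 in pair 3 (1.46 and 6.43). It stays open whether macrophages add to single genes in replicate 3. Of the 27 genes that rose in the paired fit, 9 were at least 2-fold higher in IL-1β replicate 3 than the mean of the other IL-1β libraries when 0.01 CPM was added to both (among them IL1B, CCL20, IL24, LIF and CSF2, with CCL7 just under the limit) and 8 at least 2-fold lower (among them CXCL1, CXCL6 and CSF3), and with 1 such pair, macrophages and a difference between donors cannot be told apart.

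The matrix list passed in the lower direction with camera's preset correlation but not with an estimated correlation (adjusted p = 0.344), and 24 of its 33 genes passed in neither fit. Dilution by the transcripts that rose would lower all other genes alike. On library size alone, the genes that rose in the paired fit took 4.09, 4.25 and 4.06% of counts in the controls and 10.8, 10.8 and 10.1% after IL-1β. The summed share of all other genes thereby changed by -0.104, -0.103 and -0.094 log2 units in pairs 1 to 3. The median of the 33 matrix genes lay below that level in each pair (mean difference -0.255 ± 0.109 SD, highest -0.17), and 20, 20 and 23 members lay below it, so dilution was not the whole cause. The typical gene did not fall by as much as that summed share. In the unpaired fit on library size alone, the median log2 change was -0.0083 over all tested genes and -0.309 over the matrix genes. A smaller share of fibroblasts would by itself lower all matrix genes alike if fibroblasts were their only source, a premise that was not tested. COL3A1 (0.58 ± 0.10) and DCN (0.56 ± 0.09) rose in the paired fit, in 3 of 3 pairs, while 7 genes fell. Under that premise a smaller share was not the whole cause. A part played by a smaller share of fibroblasts stays open, because markers of 5 other cell types moved both ways (35 markers, median log2 change -0.21, quartiles -0.61 and 0.36). A change of expression in the fibroblasts stays a hypothesis.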
